A study of Mus musculus with 602 samples.

How the data were processed

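The deposited values are expected counts per transcript, 1 file per cell, which the authors made by aligning reads to the mouse build mm10 with kallisto, per the submitters' processing notes. Those notes name bcl2fastq 2.18.0.12 for the conversion of base calls and give no version for kallisto. The authors left these expected counts without scaling between cells, per the file headers, and lengths and TPM in the same files were not used here. The labels differ on the library kit: the sample characteristics name Nextera XT, and the extraction text names the Nextera DNA kit. No label names a sequencing batch, and batches were not compared. By well name, the CTL animals B29, B31, B32, B33 and B34 follow each other without overlap, so they may share a plate.

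Expected counts were added over the transcripts of each gene, 85580 transcripts and 35849 genes, of which 21951 are protein coding. All transcripts were found in GENCODE M21, which gave the positions on GRCm38, the same build as mm10. Symbols were kept as labels beside the Ensembl identifiers, because 43 symbols are shared by at least 2 genes. Reads of near-identical genes, such as ribosomal protein and haemoglobin copies, may be divided wrongly between copies. A series-wide table was compared with the single-cell files for 137 columns of 2 title codes. Within a tolerance of 0.51 counts, 101 columns equalled their own cell and 36 equalled the other cell of the same code with the same well name. The single-cell files were kept as the source. The other 465 columns of that table were not compared or used.

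A cell was kept if it had at least 1000 genes with 1 count or more and at least 50000 counts. Cells were sorted singly into wells, and no doublet caller was run. 1 library stands under 2 codes, B29 and B34, with identical files, and it was left out of both. The code in each sample title was taken as the animal, because it goes with 1 age and 1 weight, except B34, in which 1 cell carries another weight. The most frequent weight was used there. The labels used here name no litter, so pups of the same litter would count as independent animals in all tests.

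Cells were clustered on log2(CPM + 1) of the 2000 most variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 1. A cluster took the name of a cell type if at least 3 of that type's markers were at least 1.5-fold higher than in the other cells and present in at least 25% of its cells. That type had to have the most such markers, and no other type more markers among the cluster's 10 leading genes. A further rule, for clusters of very low depth, left none unnamed. A cluster with a median Snap25 level of at least 100 CPM was taken as neuronal. These naming thresholds, the Snap25 threshold and the omission of haemoglobin genes from naming were chosen after the clusters were seen. A marker rule that takes no clusters, with markers at 10 CPM and 3-fold over the opposite class, served as an alternative. It also set the classes where both classes were compared with each other, among cells of the neuronal clusters.

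Counts were summed over the cells of each animal, rounded, and tested with edgeR (TMM, filterByExpr, robust quasi-likelihood fit). An animal entered with at least 5 cells, or 3 cells in the interaction and the comparison of classes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests are two-sided. Without any change, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05. The main edgeR comparisons of the groups lie under this share, and that for age lies above it. Each ± beside a log2 fold change is an approximate standard error, the absolute fold change divided by the square root of edgeR's F statistic. Each ± beside a mean is the SD over animals, or over the sums of both classes where the text says so. The interaction was fitted with the animal as a block, and the age slope with group as a term. DESeq2 was the other tool. Single values per animal, such as the share of cells with Crh, were compared by permutation of animals, with every grouping counted, so that these tests are exact. The 6 planned comparisons of this kind were adjusted together. Binomial intervals are exact at 95% and, like the limits allowed by a count of 0, cover counting error only. Crh counted as detected in a cell at 10 CPM.

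The 28 gene lists were tested with limma camera on log2 CPM (prior count 2) at the preset correlation of 0.01, and again with a correlation estimated per list and with fry, which asks whether the members of a list move on balance one way. The lists were neuropeptides and their processing, glucocorticoid receptors and response genes, CRH system receptors and binding protein, immediate early genes, heat shock and dissociation stress, neuronal immaturity and outgrowth, neuronal maturity, synaptic vesicle release, the postsynaptic density and synapse organisation, ionotropic glutamate receptors, GABA receptors and chloride transport, voltage-gated ion channels, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cytosolic ribosomal proteins, the proteasome, cholesterol synthesis, histone and chromatin modifiers, and interneuron and hypothalamic identity factors. The other 8 held markers of astrocytes, the oligodendrocyte lineage, microglia and blood immune cells, endothelial and mural cells, ependymal cells and tanycytes, erythroid cells, cycling cells, and cortical and thalamic neurons.

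Genes are named by a rule. Of the called genes with a known symbol, a mean of at least 10 CPM and detection at 1 CPM in at least 50% of the animals of the higher group, the 12 with the smallest p in each direction are named. If none pass, the 6 with the smallest p in each direction are given as values. Crh, Slc17a6, Slc32a1, Gad1, Gad2, Nr3c1, Nr3c2, Fkbp5, Crhr1 and Fos are named in every test in which they passed the filter, and up to 4 members with the smallest p from each list. Clusters are described by genes among their 10 leading ones, and cluster 4 also by Slc17a6 and Tcf7l2, chosen after their values were seen. Some of these genes are not reported. Genes called under this minimum are named where 5 or fewer were called, and these were chosen after their values were seen.

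In a self-test, 200 genes were given a known change in simulated counts with the spread of the real data. Of the genes changed 8-fold, edgeR called 4.5% in the all-cell sums, 10.6% in the neuronal clusters, 16.7% in the glutamatergic class, 4.5% in the GABAergic class, 0% in the interaction, 50% in the age slope (8-fold per day) and 27.3% in the comparison of classes. For a simulated list with members changed 2-fold, camera gave p = 3.18e-07. Genes were simulated independently of each other, so this does not show how camera performs on lists whose members vary together between animals.

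The planned comparisons, their tests, the cell filter, the gene lists, the marker lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparison within neuronal clusters, the comparison of the 2 neuron classes with each other, the gene lists outside the all-cell group comparison and the further alternatives named in the last section were chosen afterwards. Analyses were run with python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.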

Results

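The series holds Smart-seq2 libraries of polyadenylated RNA from single cells of mouse pups at P10 to P12. Cells came from Crh-IRES-Cre;Ai14 mice, in which cells with a history of Crh expression carry the red protein tdTomato. Hypothalamic slices were trimmed of thalamus and cortex and treated with papain, and red cells were sorted singly into wells. Crh encodes corticotropin-releasing hormone, which starts the hormonal stress response. Control pups (CTL) were reared in standard cages, and pups with early-life adversity (ELA) were reared with limited bedding and nesting material from P2 to P9, and those sequenced stayed on it until collection. The question stated for the series is how adversity in a sensitive period of brain development changes these cells.

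There are 602 cells under 24 codes taken as animals, 15 CTL and 9 ELA. The cell filter kept 506 cells, 258 of 284 CTL cells and 248 of 318 ELA cells. Below the count minimum lay 20 CTL and 70 ELA cells, and in L11 only 35 of 88 cells were kept. Kept cells held 88550 to 6036768 expected counts, with a median of 1160628 in CTL and 1664706 in ELA. Summed over cells, animals held from 3666240 counts (B31) to 116177903 counts (L17). The all-cell comparison used 13 CTL and 7 ELA animals, because B23, B31, L14 and L9 had fewer than 5 cells. Code letters follow the groups except for L13, a CTL animal, so only 1 animal tells a batch that follows the letter apart from group.

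The sorted cells formed 13 clusters, and Crh was concentrated in some of the neuronal ones. Crh was detected in 266 of 506 cells (52.6%) and in 243 of 312 cells of the 7 neuronal clusters (77.9%). It was present in 91.4% of the 93 cells of glutamatergic cluster 1 (exact 95% interval 83.8 to 96.2%), with a mean of 703 CPM. Ppp1r17, Scgn, Agtr1a and Scg2 were among the leading genes there. GABAergic cluster 2, led by genes that include Pgr15l, Asb4, Penk and Isl1, had Crh in 92.1% of 76 cells (83.6 to 97.0%). GABAergic cluster 7, with Nts and Lhx6, had it in 90.6% of 32 cells (75 to 98.0%), and glutamatergic cluster 13, with Reln and Npy2r, in 100% of 14 cells (76.8 to 100%). Cluster 10, led by Avp, the gene of vasopressin, had Crh in 90.9% of 22 cells (70.8 to 98.9%), and cluster 8 in 56.7% of 30 cells (37.4 to 74.5%). Crh was itself among the genes used for clustering. In an added clustering without it, the matching clusters had Crh in 91.4% (cluster 1), 93.3% (2), 87.9% (7), 91.3% (10) and 100% (13) of cells. The matches of clusters 8 and 4 had it in 55.2% and 17.8%.

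Other clusters were poor in Crh. Cluster 4 was neuronal, with the vesicular glutamate transporter gene Slc17a6 and the transcription factor genes Lhx9 and Shox2, and Crh was detected in 17.8% of its 45 cells (8.0 to 32.1%). The endothelial cluster 9 had Crh in 25.9% of 27 cells (11.1 to 46.3%), microglial cluster 11 in 25% of 20 cells (8.7 to 49.1%) and astrocytic cluster 12 in 12.5% of 16 cells (1.6 to 38.3%). Cluster 3, with astrocyte and ependymal genes, had it in 8.8% of 57 cells (2.9 to 19.3%), and cluster 6 in 11.1% of 36 cells (3.1 to 26.1%). In cluster 5, with the oligodendrocyte lineage gene Olig1, Crh was detected in 0 of 38 cells (0 to 9.3%). The median depth was 1134333 counts in non-neuronal cells and 1590105 in neuronal cells. Clusters 11 and 12 came mainly from 1 control animal, B38, with 17 of 20 and 10 of 16 cells.

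**Figure D1:**
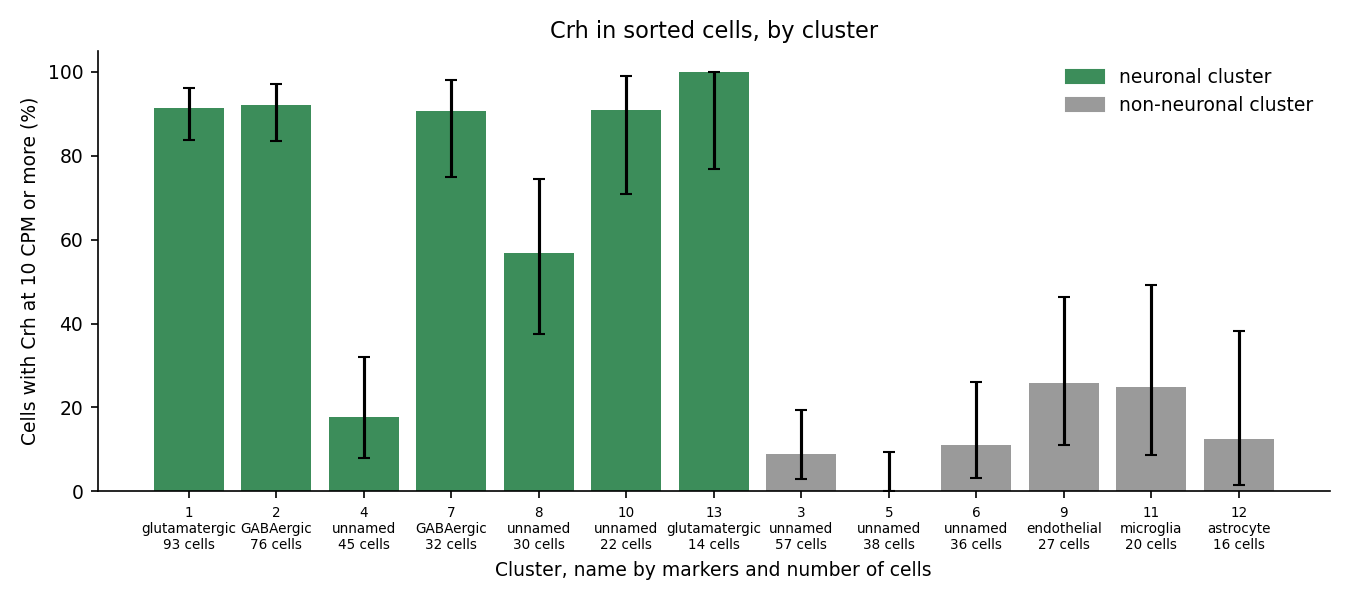
Bars show the percent of cells with Crh at 10 CPM or more (y axis) in each of the 13 clusters (x axis), green for neuronal and grey for non-neuronal clusters, with exact 95% binomial intervals as error bars. Clusters 1, 2, 7, 10 and 13 lie at 90.6% or higher, and neuronal cluster 4 at 17.8%.

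ELA pups were lighter at collection, in a test that takes each pup as independent, because litters are not known. Their sorts also held a higher mean share of neuronal cells, a difference that did not pass its test. Weight was 6.07 ± 0.495 (SD, n = 15) in CTL and 4.89 ± 0.741 (n = 9) in ELA, in a unit that the labels do not give (exact permutation p = 0.000226, adjusted p = 0.00136). Within P11, weight was 6.13 ± 0.25 (n = 4) against 4.33 ± 0.577 (n = 3), with an exact permutation p of 0.0286, the smallest possible. Within P12 it was 6.19 ± 0.458 (n = 8) against 5.20 ± 0.758 (n = 5), exact permutation p = 0.0124, and P10 held too few animals. Neuronal clusters held 50.4 ± 27.2% (SD, n = 13) of a CTL animal's cells and 73.1 ± 28.6% (n = 7) of an ELA animal's, an added comparison with exact permutation p = 0.0967. Within P11 the shares were 35.6 and 88.8% (exact permutation p = 0.1, the smallest possible) and within P12 51.2 and 76.0% (exact permutation p = 0.255). Without B20 the exact permutation p for that share was 0.0427, and without L11 it was 0.0179.

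Crh was detected in 41.4 ± 23.2% (SD, n = 13) of the cells of a CTL animal and 65.6 ± 21.9% (n = 7) of those of an ELA animal, with 6 of 7 ELA animals above the CTL mean (exact permutation p = 0.0373, adjusted p = 0.0746). Among neuronal clusters the shares were 77.5 ± 17.9% (n = 10) and 79.9 ± 12.2% (n = 6), with an exact permutation p of 0.798. Within P11 the shares were 35.0 and 69.9% (exact permutation p = 0.1, the smallest possible with 3 animals each), and within P12 they were 44.6 and 74.7% (exact permutation p = 0.109). With every cell thinned to 50000 counts the shares were 41.7 and 64.9% (exact permutation p = 0.0514). The mean level of Crh, as log2(mean CPM + 1), was 7.71 ± 0.98 (n = 13) and 8.37 ± 0.80 (n = 7), exact permutation p = 0.146 and adjusted p = 0.22. In neuronal clusters alone it was 8.83 and 8.84 (exact permutation p = 0.98). For the share of cells with Crh, leaving out 1 animal took the exact permutation p above 0.05 for B19 (0.0558), B21 (0.0524), B25 (0.0565), B28 (0.0553), B32 (0.0501), B36 (0.0564), L10 (0.0507), L12 (0.0599), L16 (0.0565), L17 (0.0609) and L7 (0.103).

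GABAergic neuron-like cells, those of clusters 2 and 7, made up 15.2 ± 11.4% (SD, n = 13) of CTL cells and 31.6 ± 19.3% (n = 7) of ELA cells per animal, with 5 of 7 ELA animals above the CTL mean (exact permutation p = 0.026, adjusted p = 0.0746). The marker rule gave 22.5 and 34.2% (exact permutation p = 0.186), and among neuronal cells the shares were 31.7 and 39.0% (exact permutation p = 0.527). Within P11 they were 10.8 and 22.4% (exact permutation p = 0.2) and within P12 18.0 and 48.4% (exact permutation p = 0.0121). The ELA animals at P12 were only L10 (52% of 25 cells), L7 (33.3% of 15 cells) and L15 (60% of 5 cells). Without L10 the exact permutation p was 0.0741, and without L15 it was 0.0857. Glutamatergic neuron-like cells, those of clusters 1 and 13, made up 15.5 ± 14.1% and 22.6 ± 25.1% (exact permutation p = 0.423, adjusted p = 0.423), and the difference of 7.11 points was 0.8745 without L7 and 3.046 without L16. Cluster 4, which took no class name, is not in this share, though the marker rule placed 44 of its 45 cells as glutamatergic. The median number of genes per cell was 6671 ± 1953 in CTL and 7784 ± 1919 in ELA animals (exact permutation p = 0.237, adjusted p = 0.284).

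**Figure D2:**
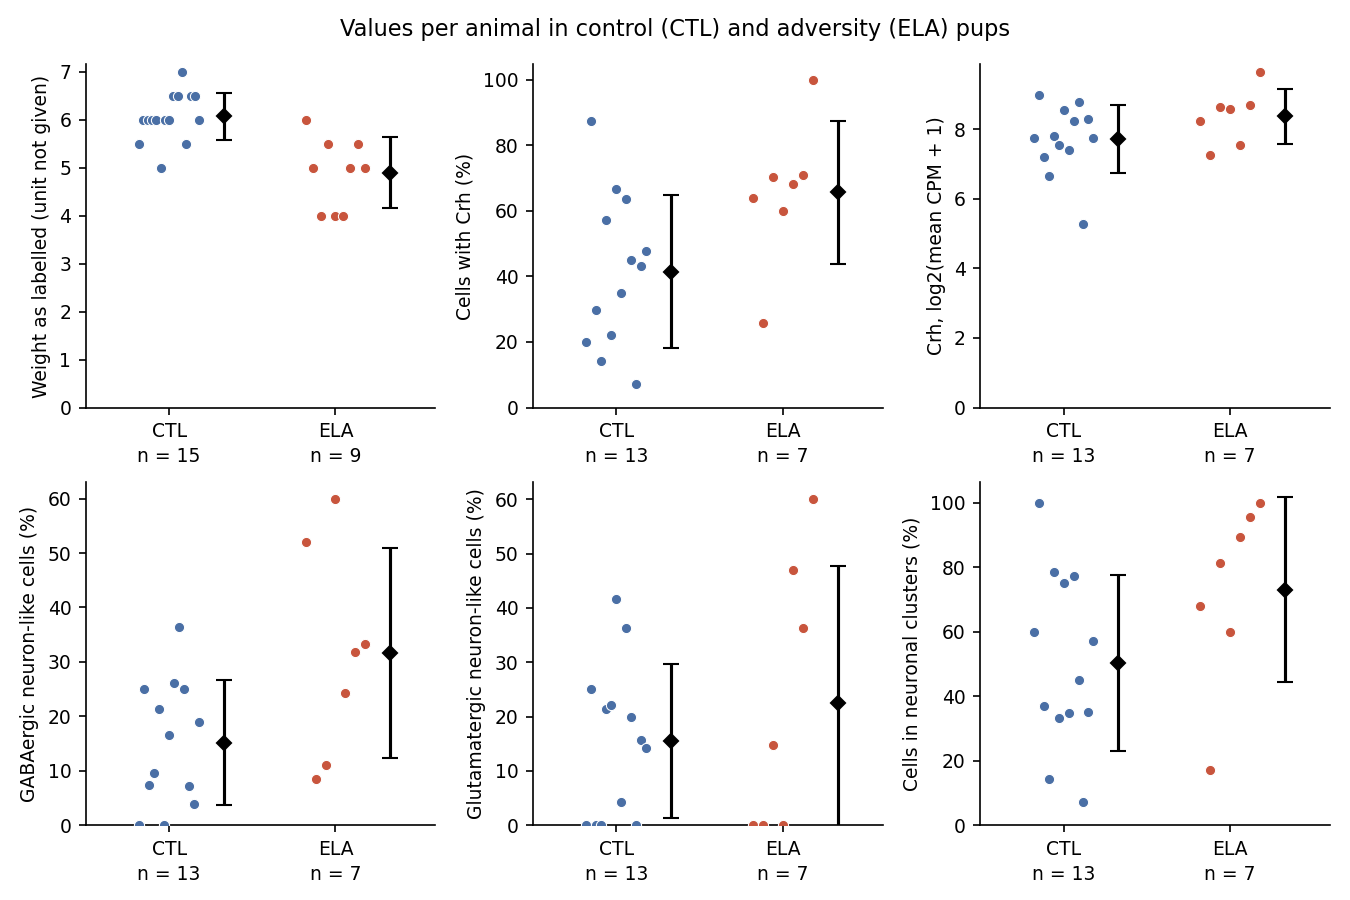
Each point is 1 animal of the CTL or ELA group (x axes), and diamonds with bars show the mean ± SD for weight, the percent of cells with Crh, Crh as log2(mean CPM + 1), and the percent of GABAergic, glutamatergic and neuronal-cluster cells (y axes). All 9 ELA weights lie below the CTL mean of 6.07, and 6 of 7 ELA animals lie above the CTL mean of 41.4% of cells with Crh.

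In sums over all cells no gene passed the test, and the genes below are those with the smallest p in each direction. Deup1, which takes part in centriole amplification in multiciliated cells, stood at 1.13 ± 1.38 CPM (SD, n = 13) in CTL and 29 ± 43.4 CPM (n = 7) in ELA, a log2 fold change of 4.67 ± 1.08. Drc3, a component of the ciliary dynein regulatory complex, stood at 11.5 ± 13.3 and 74.5 ± 103 CPM (2.70 ± 0.71), and Cdhr3, a cadherin of ciliated epithelium, at 5.53 ± 1.55. Ttr, the transthyretin gene of the choroid plexus, had a log2 fold change of 7.67 ± 1.86 that came mainly from L11. Ptprt (3.08 ± 0.85) and Spats2l (1.59 ± 0.49) followed. Toward CTL stood Lpar6 (-3.08 ± 0.86), Nectin3 (-2.08 ± 0.59), Kctd14 (-5.65 ± 1.61), the transcription factor gene Maf (-2.67 ± 0.76), Lgr4 (-2.44 ± 0.70) and Dock1 (-2.51 ± 0.83).

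On GRCm38, Deup1 (ENSMUSG00000039977.16) lies on chromosome 9 from 15559864 to 15627933, Ttr (ENSMUSG00000061808.4) on chromosome 18 from 20665280 to 20674321, and Crh on chromosome 3 from 19693401 to 19695396. Crh stood at 288 ± 177 CPM in CTL and 376 ± 219 CPM in ELA (0.38 ± 0.53). The transmitter genes had log2 fold changes of -0.09 ± 0.75 for Slc17a6, -0.05 ± 1.11 for Slc32a1, 0.44 ± 1.03 for Gad1 and 0.999 ± 0.80 for Gad2. The glucocorticoid receptor gene Nr3c1 was at 0.02 ± 0.50, the mineralocorticoid receptor gene Nr3c2 at 0.38 ± 0.93, Fkbp5 at -0.71 ± 0.98, Crhr1 at 1.601 ± 1.25 and Fos at -0.43 ± 0.36. edgeR called 0 of 20183 genes (smallest adjusted p = 0.755), with 777 at an unadjusted p under 0.05. That is fewer than the share of 0.05 that would fall there without any change. DESeq2 called 57 genes, of which 34 were higher and 23 lower in ELA.

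Between the groups, 7 of the 28 gene lists were called in the all-cell sums, 3 higher and 4 lower in ELA. Neuropeptide genes stood higher, with 23 of 29 members positive and a median log2 fold change of 0.64, led by Avp (4.19 ± 1.34) and Penk (1.76 ± 0.78), while Npy stood at -4.85 ± 2.20 (adjusted p = 0.0013, and adjusted p = 0.847 with an estimated correlation). Ionotropic glutamate receptor genes had 17 of 21 members positive, such as Gria4 (1.46 ± 0.48) and Grin3a (1.30 ± 0.47), with adjusted p = 0.0141, and adjusted p = 0.814 with an estimated correlation. GABA receptor genes had 15 of 20 members positive, such as Gabrb2 (2.92 ± 1.10), with adjusted p = 0.0309, and adjusted p = 0.959 with an estimated correlation. Astrocyte markers stood lower, with 14 of 16 members negative and a median of -0.99, such as Aldoc (-1.60 ± 0.55), Gja1 (-2.11 ± 0.73) and Slc1a3 (-1.63 ± 0.66), with adjusted p = 3.83e-05, and adjusted p = 0.814 with an estimated correlation. Immediate early genes, which respond quickly to activity or stress, had 19 of 24 members negative, such as Egr3 (-2.43 ± 1.01) and Egr1 (-1.07 ± 0.45), with adjusted p = 0.000451, and adjusted p = 0.771 with an estimated correlation. Ribosomal protein genes had 59 of 81 members negative and a median of -0.19 (adjusted p = 0.0212, and adjusted p = 0.959 with an estimated correlation). For mitochondrially encoded genes the test pointed lower, though the median was 0.02, the mean 0.06 and 8 of 13 members were positive (adjusted p = 0.0369, and adjusted p = 0.959 with an estimated correlation).

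Beside these lists, non-neuronal cells made up 53.9% of the kept CTL cells and 22.2% of the kept ELA cells. Microglia markers were negative in 14 of 14 members, with a median of -2.62 (adjusted p = 0.288), and erythroid markers were positive in 7 of 7 (adjusted p = 0.606). Endothelial and mural markers (adjusted p = 0.288), oligodendrocyte markers (0.812), ependymal markers (0.801), cycling markers (0.463) and cortical and thalamic markers (0.387) were not called. Glucocorticoid response genes were not called (adjusted p = 0.288, median 0.02, mean -0.24, with the test pointing lower), nor were the CRH system genes (0.976, median 0.17, mean -0.05), heat shock genes (0.812, median 0.14, mean -0.05), or identity factors (0.662). Adjusted p was 0.258 for neuronal immaturity, 0.387 for neuronal maturity, 0.0711 for synaptic vesicle release, 0.357 for the postsynaptic density and synapse organisation, 0.225 for voltage-gated channels and 0.0628 for cholesterol synthesis. It was 0.316 for nuclear genes of oxidative phosphorylation, 0.976 for glycolysis, 0.976 for the proteasome (median 0.03, mean -0.07) and 0.801 for chromatin modifiers. In all 28 lists, 0 members were called over all genes and 0 when adjusted over the list alone. With equal weight per cell 9 lists were called, without the ribosomal and the mitochondrial list. Gained were neuronal immaturity (adjusted p = 0.0021), synaptic vesicle release (0.00115), voltage-gated channels (0.0108) and cholesterol synthesis (0.00195), with adjusted p from 0.567 to 0.663 with an estimated correlation.

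**Figure D3:**
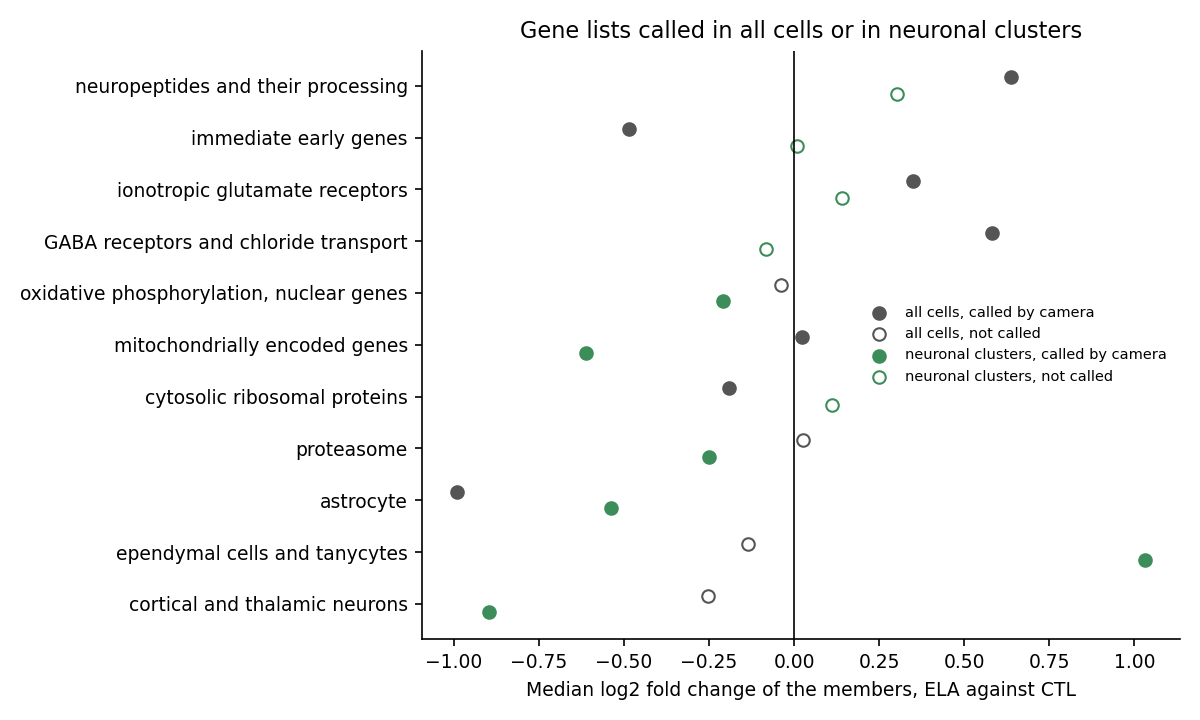
Points show the median log2 fold change, ELA against CTL, of the members (x axis) of the 11 lists called by camera in all cells or in neuronal clusters (y axis), grey for all cells and green for neuronal clusters, filled if called and open if not. Astrocyte markers lie at -0.99 in all cells and -0.54 in neuronal clusters, and neuropeptides at 0.64 and 0.30.

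Within the 7 neuronal clusters, a comparison added after the data were seen, camera placed genes of the respiratory chain lower in ELA neurons, while fry called neither of the lists (adjusted p = 0.816 for both). Mitochondrially encoded genes were negative in 12 of 13 members, with a median log2 fold change of -0.61, such as mt-Co3 (-1.22) and mt-Atp6 (-0.92), with adjusted p = 3.44e-06, and adjusted p = 0.681 with an estimated correlation. Nuclear genes of oxidative phosphorylation were negative in 60 of 79 members, with a median of -0.21 and Ndufb6 at -1.06 ± 0.43 (adjusted p = 2.47e-07, and adjusted p = 0.491 with an estimated correlation). Over all their cells, the CTL animals B29, B32, B33 and B34, all at P12, had 7.76 to 10.8% of counts from mitochondrially encoded genes, the other 6 CTL animals of these sums 2.181 to 4.438%, and the ELA animals 1.312 to 6.324%. By well name B29, B32, B33 and B34 may share a plate, which was not tested. Without these 4 animals, a setting chosen after the values were seen, the mitochondrially encoded genes were positive in 10 of 13 members and not called (adjusted p = 0.235). The animals were picked by their level of these same genes, so that change was favoured in advance and decides nothing about ELA. Without the same 4 animals the nuclear genes were negative in 61 of 79 (adjusted p = 3.14e-09, and adjusted p = 0.45 with an estimated correlation). Per animal, mitochondrially encoded genes took 4.92 ± 3.31% (SD, n = 10) of the counts of CTL neurons and 2.96 ± 2.004% (n = 6) of those of ELA neurons (exact permutation p = 0.207). Over all cells it was 5.18 ± 3.18% (n = 13) and 6.18 ± 7.83% (n = 7), exact permutation p = 0.749, with L15 at 23.4%. Without L15, which is not among the neuronal sums, the ELA value was 3.308 ± 2.08% (n = 6), exact permutation p = 0.213. Proteasome genes were negative in 23 of 36 members (adjusted p = 0.0262, and adjusted p = 0.681 with an estimated correlation). Camera also called markers of other cell types, though not with an estimated correlation. Astrocyte markers were negative in 12 of 15 members (adjusted p = 0.0262, and adjusted p = 0.894 with an estimated correlation), and cortical and thalamic markers in 6 of 9 (adjusted p = 0.0276, and adjusted p = 0.491 with an estimated correlation). Ependymal and tanycyte markers were positive in 5 of 5 members, with Crym at 3.56 ± 1.61 and Ccdc153 at 1.51 ± 0.86 (adjusted p = 0.00728, adjusted p = 0.114 with an estimated correlation, and fry adjusted p = 0.0463). With equal weight per cell fry no longer called this list (adjusted p = 0.148), and without B29, B32, B33 and B34 neither camera (0.187) nor fry (0.107) did. With equal weight per cell the proteasome and the cortical and thalamic lists were not called, and 0 list members were called when adjusted over the list alone.

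In these neuronal sums of 10 CTL and 6 ELA animals, edgeR called 1 of 16869 genes, with 391 at an unadjusted p under 0.05, and DESeq2 called 32. The gene was Kif6, a kinesin gene on chromosome 17 from 49615136 to 49909847, at 0.0198 ± 0.0523 CPM in CTL and 5.15 ± 4.91 CPM in ELA (7.46 ± 1.12, adjusted p = 0.0285). It lies under the minimum level for naming and was chosen after its value was seen. It had 5 counts in CTL sums and from 96 to 268 in each ELA sum, from 2 of 108 CTL and 11 of 185 ELA cells. CTL animals with too few neuronal cells for these sums held it in 3 of 11 cells, with 49 counts. DESeq2 also called it. In edgeR the call was lost with age as a term (adjusted p = 0.0755) and with at least 10 cells per animal (adjusted p = 0.999). It was also lost with equal weight per cell (limma adjusted p = 0.0685). Leaving out any 1 animal other than B33 lost it too (edgeR adjusted p from 0.0523 to 0.085). The log2 fold change was then 7.37 with age, 6.10 with at least 10 cells, 6.80 to 7.64 in the leave-outs that lost the call and 2.33 with equal weight. Of other genes, none passed the test: Rxrg stood at 3.32 ± 1.11, Gxylt1 at 2.52 ± 0.82, Ube4a at 2.36 ± 0.79, Acsl4 at -2.35 ± 0.70, B3galt1 at -1.58 ± 0.54, Crh at -0.17 ± 0.36 and Nr3c1 at 0.45 ± 0.50.

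In glutamatergic neuron-like cells the question was whether adversity changes the Crh cells that release glutamate, and mitochondrially encoded genes stood lower in ELA by camera. These cells are part of the neuronal sums above, as are the GABAergic cells below, and the classes share animals. They were negative in 12 of 13 members, with a median of -0.73 (adjusted p = 0.00106, and adjusted p = 0.931 with an estimated correlation). The CTL animals here were B29, B33 and B38, with 7.76, 9.3025 and 4.438% of counts from these genes over all their cells, and the ELA animals L16, L17 and L7, with 5.456, 6.324 and 2.325%. By well name B29 and B33 may share a plate. Nuclear genes of oxidative phosphorylation were negative in 49 of 78 members, such as Ndufc2 (-1.14 ± 0.33), with adjusted p = 0.0237, and adjusted p = 0.931 with an estimated correlation. Oligodendrocyte markers were negative in 11 of 13 members (adjusted p = 0.056). Leading genes, none of which passed the test, were Spg21, at 5.47 ± 2.16 CPM (SD, n = 3) in CTL and 60.4 ± 6.59 CPM (n = 3) in ELA, the polysialyltransferase gene St8sia2 (5.39 ± 1.09), Fam214a (4.47 ± 1.03), Nrip3 (1.68 ± 0.39) and Zfp27 (7.33 ± 1.71). On the other side were Cbx3, a heterochromatin protein gene (-1.58 ± 0.34), Cycs, the cytochrome c gene (-1.71 ± 0.44), Scn2b, a sodium channel subunit gene (-1.30 ± 0.36), Skil (-1.86 ± 0.46), Zfp626 (-3.49 ± 0.83) and Zfp850 (-8.72 ± 1.83).

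Zfp273 had 1 count in the CTL sums and 3194 in the ELA sums, a ratio of 911 (exact interval 163 to 36000, for counting error alone), or 304 with the CTL side set to 3 counts. Its level in ELA was 24.2 ± 28.9 CPM. Spg21 lies on chromosome 9 from 65460947 to 65488470, and St8sia2 on chromosome 7 from 73939119 to 74013690. Crh stood at 787 ± 371 and 731 ± 431 CPM (-0.11 ± 0.54), Slc17a6 at 0.17 ± 0.39, Nr3c1 at -0.03 ± 0.39 and Fos at 1.07 ± 0.52. Gad1 stood at 0.215 ± 0.316 and 9.88 ± 12.4 CPM (5.60 ± 2.07). edgeR called 0 of 16459 genes (smallest adjusted p = 0.84), with 620 at an unadjusted p under 0.05 (1367 without B33 and 1069 without B38), and DESeq2 called 358. The sums held 21 CTL and 65 ELA cells, and 0 list members were called when adjusted over the list alone.

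GABAergic neuron-like cells, the other main Crh class, had lower mitochondrially encoded genes and higher immediate early genes in ELA by camera. All 13 mitochondrially encoded genes were negative, with a median of -1.27 (adjusted p = 1.55e-07, and adjusted p = 0.964 with an estimated correlation). The 3 CTL animals of this comparison, B32, B33 and B34, all at P12 and by well name perhaps on a shared plate, had the highest percent of counts from these genes among CTL animals over all their cells, 10.3, 9.3025 and 10.8%, against 2.181 to 7.76% in the other CTL animals and 2.325 to 6.324% in the 4 ELA animals here. Adjusted over the list alone, 4 of them passed: mt-Atp8, at 1021 ± 270 CPM (SD, n = 3) in CTL and 291 ± 129 CPM (n = 4) in ELA (-1.81 ± 0.42), mt-Atp6 (-1.63 ± 0.41), mt-Co3 (-2.28) and mt-Nd2 (-1.32). Over all genes 0 of them passed. Immediate early genes were positive in 17 of 21 members, with a median of 1.24 and Nr4a1 at 3.78 ± 1.18, while Nr4a2 stood at -5.09 ± 1.74 (adjusted p = 0.0125, and adjusted p = 0.964 with an estimated correlation). Astrocyte markers were negative in 11 of 16 members (adjusted p = 0.0776), and ependymal markers were positive in 7 of 8 (adjusted p = 0.0699).

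Of single genes in this class, none passed the test. Erc1, which encodes an active zone protein, stood at 2.35 ± 0.52, Ssrp1 at 2.11 ± 0.53, Adpgk at 3.67 ± 0.93, Ankrd35 at 6.53 ± 1.66 and Zfp212 at 6.14 ± 1.71. Adam10, a membrane protease gene, stood at -1.62 ± 0.36, Gnl3l at -1.18 ± 0.29, Kcnip4 at -1.58 ± 0.42 and Pura at -1.62 ± 0.42. Zfp82 had 2 counts in CTL sums and 2173 in ELA sums, a ratio of 279 (exact interval 77.2 to 2310, for counting error alone), or 186 with the CTL side set to 3 counts. Crh stood at 546 ± 151 and 282 ± 140 CPM (-0.96 ± 0.43), Gad1 at -1.06 ± 0.36, Gad2 at -0.19 ± 0.36 and Crhr1 at 3.62 ± 1.69. Erc1 lies on chromosome 6 from 119570796 to 119848167, and Adam10 on chromosome 9 from 70678997 to 70780229. edgeR called 0 of 16688 genes (smallest adjusted p = 1), with 597 at an unadjusted p under 0.05, and DESeq2 called 103. With age as a term edgeR called mt-Co3 alone (-4.52 ± 0.42), a gene chosen after its value was seen.

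The effect of ELA was then compared between both classes in 4 CTL and 4 ELA animals, as the effect in glutamatergic minus that in GABAergic cells. Gad1, which makes GABA, led with a difference in log2 fold change of 6.55 ± 1.56, and the splicing factor gene Sf3b1 (1.59 ± 0.48), Akap6 (2.28 ± 0.72) and Sox11 (1.52 ± 0.50) followed. Gad1 was near 0 in CTL glutamatergic cells, as given above (0.215 ± 0.316 CPM, n = 3). Fank1 (27.6 ± 54.0 CPM in CTL and 13.2 ± 11.5 CPM in ELA) and Alg13 (12.2 ± 26.4 and 11.8 ± 11.9 CPM) were also among the leading 6, with mean and SD over 8 sums per group, 1 for each class of each animal. In the other direction stood Gpc5 (-6.83 ± 2.07), the calcium-binding protein gene Calb2 (-4.08 ± 1.24), Rasd1 (-6.60 ± 2.01), Adcy3 (-7.46 ± 2.47), Etfa (-3.02 ± 1.06) and Sowaha (-4.43 ± 1.64). Crh stood at 0.76 ± 0.53, and Gad1 lies on chromosome 2 from 70553072 to 70602014. edgeR called 0 of 12754 genes (smallest adjusted p = 1), with 187 at an unadjusted p under 0.05, and DESeq2 was not run for this comparison.

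Over the 3 days of age from P10 to P12, with group as a term, mitochondrially encoded genes stood higher and microglia, ependymal and cortical or thalamic markers lower by camera, and no list was called with an estimated correlation. All 13 mitochondrially encoded genes were positive, with a median slope of 0.80 log2 per day, such as mt-Nd4l (1.08 ± 0.32) and mt-Co3 (1.28 ± 0.44), with adjusted p = 0.00712, and adjusted p = 0.99 with an estimated correlation. Adjusted over the list alone 9 of them passed. The CTL animals with the highest percent of counts from these genes, B32, B33 and B34 at 10.3, 9.3025 and 10.8%, and L15 at 23.4%, were all collected at P12. By well name B32, B33 and B34 may also share a plate. Microglia markers were negative in 14 of 14 members, with a median of -1.91 (adjusted p = 0.0404, and adjusted p = 0.99 with an estimated correlation), and adjusted over the list alone 1 passed, the lysozyme gene Lyz2 (-6.12). Ependymal markers were negative in 11 of 12 members, with a median of -0.72 (adjusted p = 0.00712, and adjusted p = 0.99 with an estimated correlation). Of the animals used only B19, B26 and L11 were at P10. Without L11, a setting chosen after the values were seen, the ependymal list was called (adjusted p = 0.0437, and adjusted p = 0.821 with an estimated correlation), and the mitochondrially encoded (0.332) and microglia (0.201) lists were not. Cortical and thalamic markers were negative in 7 of 10 members, such as Tcf7l2 (-1.09 ± 0.36), with adjusted p = 0.00712, and adjusted p = 0.316 with an estimated correlation. In the heat shock list 1 member passed when adjusted over the list alone, Ddit3 (-1.21), a symbol shared by more than 1 gene.

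No single gene passed the test for age. Sirpa, a receptor gene of myeloid cells and neurons, had the smallest p, at -1.18 ± 0.24 log2 per day (adjusted p = 0.376), and lies on chromosome 2 from 129592835 to 129632228. Sirt4 stood at -1.68 ± 0.37, Kctd14 at -2.33 ± 0.52, Cdpf1 at -1.49 ± 0.33, Brd7 at -1.15 ± 0.26 and Cep63 at -1.53 ± 0.35. Adal stood at 2.64 ± 0.62, Maea at 1.24 ± 0.30, Ccdc47 at 0.86 ± 0.23, the neuropeptide Y receptor gene Npy2r at 3.09 ± 0.87, Tmtc1 at 3.14 ± 0.89 and Thsd7a at 1.84 ± 0.53. Crh stood at 0.36 ± 0.35 and Gad1 at 1.36 ± 0.67. edgeR called 0 of 20183 genes, with 1571 at an unadjusted p under 0.05 (915 without B19, 1 of 3 animals at P10), and DESeq2 called 323. Without the filter on low counts edgeR called 5 genes, which lie under the minimum level for naming and were chosen after their values were seen: Wfdc2 (-5.87), Sprr1a (-5.96), Gm19410 (-5.55), 2300002M23Rik (-5.31) and AC132455.1 (-5.81).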

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

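The planned tests here are the counts of genes, the all-cell gene lists and the levels of genes named in every test; the percent of cells passing the cell filter, the mitochondrial percent, the level of Ttr, all tests that weigh an explanation, apart from the class exchanges for the gene lists, and all results in neuronal clusters were chosen only after the result was seen.

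Among 32 groups of 4 to 10 animals, 6 held an animal whose gap to its nearest neighbour exceeded Dixon's 95% critical value. Chance gives about 1 in 20 groups. All groups tested were ELA groups, because every CTL group held more than 10 animals, so CTL animals were not screened for outliers. In L11, 39.77% of cells passed the cell filter, against 82.5 to 100% in the other ELA animals. In L15, 23.4% of counts came from mitochondrially encoded genes, against 1.312 to 6.324%. Ttr stood at 12.53 log2(CPM + 1) in L11, against 0 to 4.875. Gad1 stood at 0.2092 log2(CPM + 1) in L12, against 4.638 to 7.204, and Gad2 at 2.316 in the same animal, against 6.662 to 9.643. Nr3c1 stood at 2.344 log2(CPM + 1) in L15, against 5.826 to 8.312.

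The first pattern weighed is the 7 gene lists called in the all-cell sums, neuronal lists higher and astrocyte markers lower in ELA. A different share of non-neuronal cells in the groups may account for part of them, since 2 of the 7 were called again in the same direction in sums of the neuronal clusters. Those sums also leave out B25, B28, B36 and L15, and over all cells of the animals that remain 5 of the 7 were called again, so the change of animals goes with part of the loss. Members of a list that vary together between animals are a second candidate explanation, since 0 of the 7 were called with a correlation estimated per list. Chance division of the animals cannot be excluded: 52 of 100 splits gave as many lists, and the highest other split gave 15 against the real 7. An effect of ELA on these genes stays open as untested apart from these, as do batches that follow the code letters.

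The second pattern is the 57 genes that DESeq2 called in the all-cell sums where edgeR called 0, with 777 at an unadjusted p under 0.05. Removal of low genes by edgeR's filter is argued against as the whole cause, because 63.2% of the 57 had been tested by edgeR. A level that rests on 1 animal is a candidate for some of these calls: in 50.9% of them 1 animal held over 50% of the higher group's level. The share was 17.4% among the genes not called, counted only over genes that edgeR had tested. The calls were not limited in this way, so the sets are unlike and this contrast cannot decide the question. The same shares were 84.4 and 18.6% in the neuronal clusters, where edgeR had tested only 10 of the 32 calls. These shares were 70.9 and 59.2% in the glutamatergic class, and 50.5 and 53% in the GABAergic class, where calls did not stand out in this way. Of the 36 all-cell calls that edgeR tested, 33 had an unadjusted p under 0.05 in edgeR. Which of the calls reflect ELA was not tested, and stays open.

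The third pattern is the cells without Crh in a sort on a Crh-driven reporter, of which cluster 4 is the neuronal example. Too few counts per cell is argued against, since after thinning all cells to 50000 counts 15.6% of the cells of cluster 4 had Crh, against 86.4% or more in clusters 1, 2, 7, 10 and 13. As hypotheses, these cells may have expressed Crh earlier in development, because a recombined reporter stays on, or may have entered the sort without the reporter. Neither was tested, and tdTomato transcripts were not analysed here. Tcf7l2, one of the cortical and thalamic markers, was present at 10 CPM in 100% of the cells of cluster 4. In the other neuronal clusters it was present in 14.3% (cluster 13) to 45.2% (cluster 1) of cells. In non-neuronal clusters it was present in 85.2% (cluster 9) to 100%. Where the cells of cluster 4 lay in the slices was not tested.

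The real groups were set against other splits of the animals. For genes in the all-cell sums edgeR called 0 (777 at an unadjusted p under 0.05, and 57 by DESeq2), so all 100 of 100 splits gave as many by construction, and the highest other gave 15, in 1 of the 4 other splits with any gene. For lists in the neuronal clusters 4 of 100 splits gave the real 6 or more, with another at 6. In a second draw 11 of 100 did, with another at 11, so chance could not be excluded. Camera called at least 1 list in 85 of the other splits in the first draw and in 77 in the second. For lists in the all-cell sums it did so in 98 of the other splits. For genes in the neuronal clusters, 2 of 100 splits gave the real count of 1 gene, with the highest other at 1, and 1 of 100 in the second draw, with the highest other at 0. Few splits call any gene at this threshold, so this adds little to the adjusted p of Kif6, and chance is left open for a call that leaving out most single animals moves to adjusted p of 0.0523 to 0.085, with log2 fold changes of 6.80 to 7.64. In the glutamatergic class the 10 splits are too few for a share under 0.05, with 0 genes by edgeR (620 at an unadjusted p under 0.05, and 358 by DESeq2) and 0 in the highest other. In the GABAergic class 35 of 35 splits gave as many as the real 0 of edgeR (597 at an unadjusted p under 0.05, and 103 by DESeq2), with the highest other at 1. For the interaction 35 of 35 gave as many as the real 0 of edgeR (187 at an unadjusted p under 0.05), with the highest other at 0. Any split reaches a count of 0, so these splits do not bear on chance.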

How the results depend on the processing

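The neuronal-cluster results, the glutamatergic against GABAergic comparison, the lists by age, the settings limited to some cells, the list tests in fewer animals, the shares within an age, the mitochondrial percent and the shares with 1 animal left out are tests chosen only after the result was seen; the others were planned. In the all-cell sums edgeR called 0 genes (777 at an unadjusted p under 0.05), DESeq2 57, and edgeR in neuronal clusters only 1. In neuronal clusters, edgeR's 1 became 32 with DESeq2, 0 with age in days as covariate (Kif6 at 7.37 log2), with limma at equal weight per cell (2.33 log2), with at least 10 cells per animal (6.10 log2, edgeR adjusted p = 0.999) and with a mean CPM of at least 10 (which leaves out Kif6, at 1.944 CPM), and 0 to 1 with 1 animal left out. DESeq2 called 358 genes in glutamatergic cells, 103 in GABAergic cells (edgeR with age called 1) and 323 for age (edgeR without a filter on low counts called 5). Between the classes, edgeR called 12 genes without a filter on low counts, 5 without a minimum of Crh and 0 to 4 with 1 animal left out (4 without L10), and DESeq2 called 386. At least 10 cells of the class per animal was not run, because only ELA animals reached it. Of the all-cell lists, 0 were called with an estimated correlation, 0 with fry and 4 in cells with Crh; in neuronal clusters these tests gave 0 and 1 of the lists, and between classes 0 and 0. All cells of the animals in the neuronal sums gave 6 lists, and the neuronal sums without B29, B32, B33 and B34 gave 3. For age, 4 lists became 0 with an estimated correlation and stayed 4 without L11, of which 2 were other lists.

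The difference in the percent of cells with Crh, ELA minus CTL, was 24.2 points, 22.01 at 1 CPM, 23.17 with thinned counts, 34.84 within P11, 30.09 within P12, 2.435 in neuronal clusters only, and 18.44 (without L7) to 30.82 (without L11) with 1 animal left out. For GABAergic cells it was 16.39, with 11.7 by the marker rule, 11.17 with at least 10 cells per animal, 7.327 among neuronal cells, 11.58 within P11, 30.49 within P12, and 11.66 (without L15) to 20.23 (without L11) with 1 animal left out. For glutamatergic cells it was 7.112, with -0.0271 among neuronal cells, 12.65 by the marker rule, 12.36 with at least 10 cells per animal, 22.68 within P11, 1.3 within P12, and 0.8745 (without L7) to 10.87 (without L10, L11 or L15) with 1 animal left out, and 3.046 without L16. For neuronal clusters it was 18.24 (without L7) to 32.05 (without L11). The percent of counts from mitochondrially encoded genes differed by 0.9996 over all cells, 0.5903 within P11, 3.169 within P12 and -1.967 in neuronal clusters only, where L15 is not used; it was -1.87 (without L15) to 1.811 (without L11) with 1 animal left out, and -3.779 within P12 without L15. The cause of these differences between settings was not tested.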

Other observations

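All tests in this part were chosen only after the result was seen, apart from the class exchanges for the gene lists, whose expected outcome was written before they were run.

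Neurons with Crh were compared within animals between a glutamatergic and a GABAergic class, and no gene passed the test. The marker rule set the class of each cell, over all neuronal clusters, so cells of clusters without a class name could enter. The rule uses Slc17a6, Slc17a7, Slc17a8, Slc32a1, Gad1 and Gad2, and these were left out of the tests. Sim1, Dlx5 and Dlx6 took no part in the rule. The classes still come from the same expression values, so p values may be too small by an unknown amount. In glutamatergic cells Avp stood at 415 ± 477 CPM (SD, n = 7 animals) against 1.97 ± 2.40 CPM in GABAergic cells of the same animals, a log2 fold change of 8.50 ± 1.12. Sim1, a transcription factor gene of the paraventricular nucleus, stood at 42.8 ± 17.4 against 0.107 ± 0.140 CPM (8.93 ± 1.33), Scg2, a granin of secretory vesicles, at 2206 ± 965 against 547 ± 144 CPM (1.93 ± 0.30), and Tmem176b at 9.46 ± 1.26, Tmem176a at 8.25 ± 1.46 and Resp18 at 1.14 ± 0.21. Toward GABAergic cells stood Dlx5, at 62.7 ± 39.1 against 0.273 ± 0.676 CPM (-10.72 ± 1.49), Dlx6 (-4.81 ± 0.80), the receptor gene Pgr15l (-6.62 ± 0.77), Syt1, the calcium sensor of vesicle release (-1.44 ± 0.21), Sox11 (-1.84 ± 0.28) and Zfhx3 (-3.49 ± 0.56). Crh stood at 0.56 ± 0.30. edgeR called 0 of 13462 genes (smallest adjusted p = 0.0809), with 554 at an unadjusted p under 0.05, and DESeq2 called 386. All 64 of 64 exchanges of the classes within animals gave as many genes as the real 0, by construction, with the highest other at 0, which does not bear on chance. Without the minimum of Crh per cell edgeR called Scg2 (1.64), Lhx6 (-8.39), Avp (8.57), Dlx5 (-10.96) and Pgr15l (-6.73), and without L10 it called Scg2 (2.175), Dlx5 (-11.79), Syt1 (-1.58) and Pgr15l (-6.61).

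Adjusted over the list alone, neuropeptide genes had 4 members higher in glutamatergic cells (Avp, Scg2, Gal at 2.176 and Pdyn at 3.62) and 2 lower (Nts at -8.77 and Pnoc at -5.50). Identity factors had 3 higher (Sim1, Otp at 6.97 and Arnt2 at 2.93) and 4 lower (Dlx5, Dlx6, Lhx6 at -7.19 and Meis2 at -5.23). Of the 28 lists 8 were called by camera between the classes. Genes of the postsynaptic density and synapse organisation were negative in 20 of 25 members, with Nrxn3 at -1.39 (adjusted p = 0.00578, and adjusted p = 0.215 with an estimated correlation). Neuronal maturity genes were negative in 19 of 22 (adjusted p = 0.00578, and adjusted p = 0.391 with an estimated correlation) and immaturity genes in 17 of 21 (adjusted p = 0.00608, and adjusted p = 0.447 with an estimated correlation). GABA receptor genes were negative in 14 of 19 members (adjusted p = 0.0208, and adjusted p = 0.391 with an estimated correlation), ionotropic glutamate receptor genes in 14 of 21 (adjusted p = 0.0306, and adjusted p = 0.447 with an estimated correlation) and identity factors in 10 of 16 (adjusted p = 0.035, and adjusted p = 0.429 with an estimated correlation). Ribosomal protein genes were positive in 71 of 81 members (adjusted p = 0.0208, and adjusted p = 0.681 with an estimated correlation) and immediate early genes in 16 of 20, with Jun at 1.21 (adjusted p = 0.0306, and adjusted p = 0.677 with an estimated correlation). Of the 64 exchanges of classes within animals 1, the real one, gave 8 lists, and the highest other gave 7. The classes were set from expression values of the same cells, so they may differ more than exchanged ones by construction. The exchanges therefore do not exclude chance.

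Genes with a role in motile cilia among the leading ones of the all-cell comparison, and Ttr, were also counted by cell, at 1 count or more, over pooled cells and without a test. Cells outside the neuronal clusters held a median of 973225 counts in CTL and 1710088 in ELA, so detection is not on equal terms. The list of ependymal markers had 6 members positive and 6 negative in the all-cell sums. Of the 55 ELA cells outside the neuronal clusters 29 came from L11. Deup1 was detected in 17 of 139 CTL cells (12.2%) and 17 of 55 ELA cells (30.9%) outside the neuronal clusters, and in 15.1% and 16.6% of neuronal cells. Of the ELA cells outside the neuronal clusters, L11 held it in 9 of 29 and the other ELA animals in 8 of 26. Cdhr3 was detected in 5.8% and 18.2% of cells outside the neuronal clusters, and Drc3 in 57.6% and 69.1% of these and in 56.3% and 55.4% of neuronal cells. Ttr was detected in 9 of 119 CTL (7.6%) and 61 of 193 ELA cells (31.6%) of the neuronal clusters, of which 33 came from L16, 24 from L17 and 0 from L11. Outside the neuronal clusters it was detected in 32 of 139 CTL and 18 of 55 ELA cells.

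The library that stands under both B29 and B34 held 1148218 counts. Cells A8 and A9 of B21 had a Pearson r of 0.985 across genes in log2 CPM and cells A4 and A5 of L12 one of 0.96, while the next pair had 0.874. Genes are not independent replicates, and these pairs were kept. Haemoglobin gene Hba-a2 was detected at 10 CPM in 30% to 100% of the cells of each cluster. As a value beside the sort, the share of cells of cluster 4 was 6.14 ± 5.51% (SD, n = 13) in CTL and 7.58 ± 9.98% (n = 7) in ELA (exact permutation p = 0.681).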
